A study of Arabidopsis thaliana with 27 samples.

How the data were processed

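RNA from Arabidopsis roots was measured on 27 Affymetrix ATH1 arrays, 1 array per sample. Plants grew on MS medium with 4.5% sucrose under 16 h light and 8 h dark. The deposited values are MAS5 signal intensities, 1 per probe set on a linear scale, which the authors scaled so that the 2% trimmed mean was about 100.0 on every array. The MAS5 version and settings are not given in the sources used here. The labels do not say whether cells were sorted, nor whether replicates came from independent cultures, so the p-values measure the spread between these samples. The number of arrays per group limits the precision.

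Values were used as deposited, with no further scaling. A pseudocount of 2.37, the 10th percentile of all values, was added before taking log2. After leaving out 64 control probe sets, 22746 were tested. The annotation used assigns 1 gene to 13513 probe sets, several genes to 503 and none to 8794. Genes were named only for probe sets with 1 gene. The genes SCR, GL2 and AHK4 (WOL), whose promoters drive 3 of the markers, were not analysed here because no probe set is assigned to them.

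A linear model was fitted to the 15 arrays of the marker lines and another to the 12 stage arrays, with a mean per group, in limma 3.58.1 under R 4.3.3. Variances were moderated with an intensity trend, and Benjamini-Hochberg adjusted p-values were tested at 0.05. Each line was compared with the mean of the other 4 lines. J0571 was also compared with SCR, GL2 with J3411, and the 3 stages with one another, which makes 10 comparisons. Before the data were examined, the following were chosen: groups, comparisons, test, threshold, named-gene rule, 24 gene lists and most alternatives. The rule names, for each comparison, up to 10 genes with the largest rise and 10 with the largest fall. These had to pass the threshold, have 1 gene per probe set and show all arrays of one group on the same side of the other. The rule also allows up to 4 members with the smallest adjusted p of each list described. Fewer are named, in rank order, and among list members those whose call held under the alternatives were preferred, which favours stable genes.

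Gene lists were tested with camera in limma at a preset correlation of 0.01 and adjusted over 28 lists with at least 5 genes measured. Of these, 3 were fixed before the data were examined: cortex, expansins and XTHs, and auxin response. The other 25 were written after reading the annotation and before any group difference was seen. Each test was repeated with a correlation estimated from the data. Lists with fewer than 5 genes measured were not tested as lists.

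Signals were compared with a background of 14.78, the 95th percentile of 12 unspiked bacterial control probe sets, a level chosen after seeing the data. Where the low side of a fold lies at background, the fold of the geometric means, with low signals raised to background, is given as a lower bound ("at least"). Genes are ranked by the fitted log2 difference, which for signals near background depends on the pseudocount, so their order is not fixed. Arrays were also split into spike-in classes at the largest gap of the cre control signals, which was chosen after seeing the data. In the line comparisons, only SCR has arrays of the low class.

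The pipeline was tested on simulated data with 200 changed probe sets. It recovered 55.2% to 98.5% of changes of 4-fold or more and 11.9% to 35.8% of 2-fold changes, and at most 8.9% of its calls were false. The simulated noise was normal and independent between probe sets, with no spike-in class and no effect of the replicate number. These rates therefore test the code and need not hold for the real calls. Alternatives were no pseudocount, a pseudocount of 11 (the 25th percentile), quantile normalization, a filter on dim probe sets, no intensity trend, calls of at least 2-fold, the replicate number as a block, each array left out in turn, all arrays in one fit, and comparisons among Columbia lines only. Added after seeing the data were the spike-in class as a block, each class alone, and WOL against GL2 only.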

Results

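RNA from Arabidopsis roots was hybridised to 27 ATH1 arrays. There were 15 arrays from 5 GFP marker lines with 3 arrays per line. By their labels, J3411 marks the lateral root cap plus epidermis, SCR the endodermis and quiescent centre, and WOL the stele. GL2 marks atrichoblasts, the epidermal cells that form no hair, and J0571 marks endodermis, cortex and quiescent centre. The background is C24 for J3411, Landsberg for SCR and Columbia for WOL, GL2 and J0571. SCR replicate 1 has no tissue label. Columbia root segments gave the other 12 arrays, 4 per stage. Stage I ends near 0.15 mm above the tip, at the point of full root diameter. Stage II ends near 0.3 mm, where elongation begins. Stage III covers 0.45 mm up to 2 mm, where hairs have finished growing. The median signal per array was between 27.3 and 43.7. The small number of arrays per group limits the precision of every difference.

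Several control signals differed between arrays of the same group. The cre spike-in controls fell into a low class of 8 arrays and a high class of 19. Replicates 1 and 2 of each stage and replicates 2 and 3 of SCR were in the low class. The GAPDH 3'/5' signal ratio, a sign of RNA or labelling quality, was 4.34 to 7.85 on the 6 low-class stage arrays and 14.9 to 31.8 on the 6 high-class stage arrays. It was 1.03 ± 0.272 (SD, n = 3) in J3411, 2.03 ± 1.80 in SCR, 0.990 ± 0.230 in WOL, 1.32 ± 0.548 in GL2 and 0.992 ± 0.0761 in J0571. The actin 3' control signal was 105 to 153 in J3411 and 209 to 258 in J0571, against 855 or more on all other arrays.

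**Figure D1:**
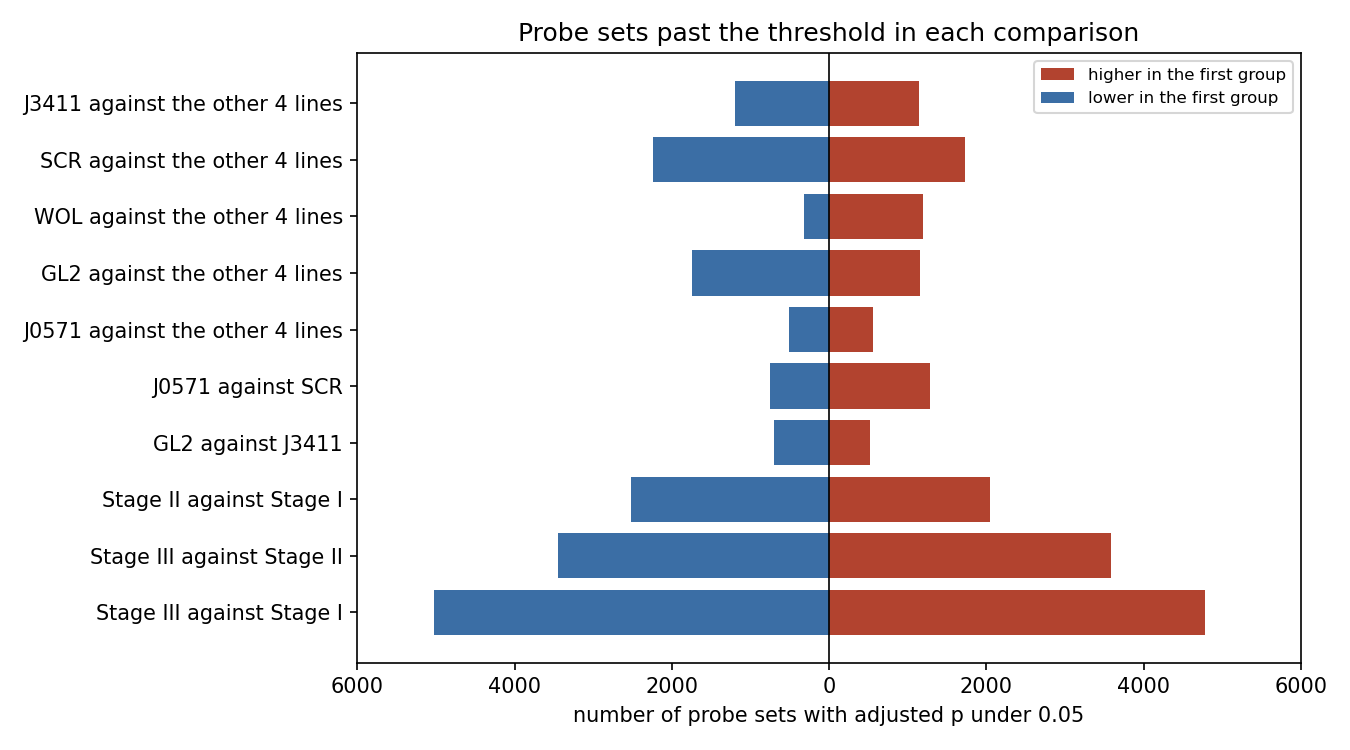
Number of probe sets with a limma adjusted p under the threshold in each of the 10 comparisons (x axis, counts), higher in the first group to the right and lower to the left. Stage III against Stage I had the most, 4779 higher and 5027 lower, and J0571 against the other 4 lines the fewest, 555 higher and 511 lower.

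The first comparison asked what the lateral root cap and epidermis marked by J3411 express in relation to the other 4 lines. Root cap genes and genes of ER bodies, the glucosidase-filled compartments of Brassicaceae cells, were higher in J3411. Genes of the endodermal barrier were lower. With an estimated correlation the ER body call held, and those of root cap (adjusted p = 0.105) and barrier genes (adjusted p = 0.0587) were lost. First by fitted log2 gain was AT1G50050, with a signal of 628 ± 615 (SD, n = 3) against 8.32 ± 7.15 (n = 12), at least 20.23-fold. AT5G44440 followed, with 538 ± 155 against 21.1 ± 17.39, at least 22.7-fold. First by fitted log2 loss was AT1G62480, at 4.39 ± 1.87 against 869 ± 1181 and at least 16.0-fold lower. RALFL32, of a family of secreted signalling peptides, followed at 2.05 ± 1.27 against 205 ± 177 and at least 10.3-fold lower.

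Of the 8 root cap genes measured, 6 were higher in J3411 and 0 lower, with a mean log2 difference of 2.46 (adjusted p = 7.16e-08, and adjusted p = 0.105 with an estimated correlation). Among them, the SKU5-similar gene sks15 had a signal of 2643 ± 858 (SD, n = 3) against 395 ± 428 (n = 12). AT4G04460, which encodes the aspartic protease PASPA3 of dying root cap cells, had 496 ± 168 against 128 ± 145. Of 7 ER body genes, 5 were higher and 0 lower, by a mean of 1.22 (adjusted p = 4.4e-06, and adjusted p = 0.0326 with an estimated correlation). PYK10, the main beta-glucosidase of root ER bodies, was at 4737 ± 513 against 2251 ± 2228, and its regulator NAI1 at 423 ± 102 against 187 ± 158. Touch, wound and elicitor genes were higher in 8 of 17 cases and lower in 0, by a mean of 1.01 (adjusted p = 1.02e-07, and adjusted p = 0.105 with an estimated correlation). WRKY6, a transcription factor of the stress response, was at 1863 ± 772 against 469 ± 186.

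Genes of suberin and the endodermal barrier were lower in J3411 in 5 of 10 cases and higher in 0, with a mean log2 difference of -2.001 (adjusted p = 4.11e-07, and adjusted p = 0.0587 with an estimated correlation). The class III peroxidase AT4G11290 was at 15.2 ± 21.2 (SD, n = 3) against 1248 ± 1156 (n = 12), at least 16.5-fold lower. GSO1, a receptor kinase needed for an intact Casparian strip, was at 29.0 ± 8.14 against 496 ± 465. In the cortex list of 5 genes, 3 were lower and 0 higher, and the same counts held adjusted over the list alone, with a mean of -1.42 (adjusted p = 0.000343, and adjusted p = 0.0326 with an estimated correlation). Its member JKD, a zinc finger protein of the ground tissue, was at 4.23 ± 1.96 against 35.7 ± 36.2. Heat shock genes also passed the set test with 1 of 13 lower and 0 higher, by a mean of -1.34 (adjusted p = 0.000982, and adjusted p = 0.821 with an estimated correlation). That comparison includes SCR, where the list was high on replicates 2 and 3, and within the high spike-in class, without these arrays, the mean was -0.73 (adjusted p = 0.0362).

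Weaker list calls in J3411 were those of 55 class III peroxidases (2 higher, 11 lower, mean -0.52, adjusted p = 0.0134, and adjusted p = 0.723 with an estimated correlation), 7 tubulins (0 higher, 1 lower, mean -0.57, adjusted p = 0.0116, and 0.642 with an estimated correlation) and 13 replication and histone genes (0 higher, 1 lower, mean -0.39, adjusted p = 0.0464, and 0.642 with an estimated correlation). The peroxidase call was lost without J3411 replicate 2 (adjusted p = 0.0542), and the tubulin call without J3411 replicate 1 or 2 (adjusted p up to 0.0892). The histone call was lost without 9 different arrays (adjusted p up to 0.212): J3411 replicates 1 and 2, SCR replicate 3, WOL replicates 1 and 3, GL2 replicates 2 and 3, and J0571 replicates 1 and 2. It was also lost after quantile normalization (adjusted p = 0.0595), with the spike-in class as a block (adjusted p = 0.0769) and within the high class (adjusted p = 0.0635). Over all 22746 probe sets tested, limma called 2341 different in J3411, 1141 higher and 1200 lower. Without J3411 replicate 1 it called 1195 and without replicate 2 it called 1155, but without replicate 3 it called 3057. Replicate 3 stood apart from the other J3411 arrays. Its mean correlation with its own group was 0.908, against 0.93 for replicate 1 and 0.931 for replicate 2. Its root hair list mean (log2) was 7.52, against 4.50 and 4.60. J3411 is the only C24 line by its labels, so cell type and background differ together.

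SCR was compared with the other 4 lines to find genes of the endodermis and quiescent centre. Endodermal barrier genes were higher in SCR, and so were most genes of the cortex list, though its marker CO2 was near background. Heat shock genes were higher on 2 of its 3 arrays. Most ribosomal protein genes were lower. Cell division genes and ER body genes were lower as lists, with only part of their members past the threshold. With an estimated correlation the SCR list calls were all lost (adjusted p = 0.107 to 0.676). The class III peroxidase AT4G36430 ranked first by fitted log2 gain, with a signal of 813 ± 267 (SD, n = 3) against 66.2 ± 66.3 (n = 12), followed by AT3G29410 (643 ± 224 against 53.7 ± 62.8) and the peroxidase Prx37 (1083 ± 222 against 199 ± 248). AT2G07777 ranked first by fitted log2 loss, at 3.57 ± 1.44 against 119 ± 43.3 and at least 7.58-fold lower. These 4 genes also passed within the high spike-in class, where SCR replicate 1 stands alone and is assumed to vary like the other groups, with log2 differences of 4.16 for AT4G36430, 3.58 for AT3G29410, 4.36 for Prx37 and -3.95 for AT2G07777.

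Suberin and endodermal barrier genes were higher in SCR in 6 of 10 cases and lower in 0, with a mean log2 difference of 2.05 (adjusted p = 2.64e-08, and adjusted p = 0.107 with an estimated correlation). Within the high spike-in class their mean was 2.27 (adjusted p = 1.54e-06). GSO1 was at 969 ± 167 (SD, n = 3) against 261 ± 386 (n = 12), AT4G11290 at 2652 ± 746 against 589 ± 799. The dirigent protein gene AT2G39430, of a family that guides lignin coupling, was at 1723 ± 452 against 504 ± 740. In the cortex list, 4 of 5 genes were higher and 0 lower, or 4 higher and 1 lower adjusted over the list alone, by a mean of 1.02 (adjusted p = 0.0122, and adjusted p = 0.161 with an estimated correlation). The cortex mean was 1.00 within the high class, where the call was lost (adjusted p = 0.109). AT1G09750 of this list was at 113 ± 17.5 against 65.7 ± 90.7, with a log2 difference of 1.54 and no call within the high class (adjusted p = 0.0849). UDP-glycosyltransferase genes were higher in 16 of 47 cases and lower in 2, by a mean of 0.57 (adjusted p = 0.000146, and adjusted p = 0.167 with an estimated correlation), and by 0.39 within the high class (adjusted p = 0.228). UGT87A2 was at 271 ± 90.8 against 68.4 ± 28.5.

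Of 121 cytosolic ribosomal protein genes, 91 were lower in SCR and 0 higher, by a mean log2 difference of -0.92 (adjusted p = 1.74e-26, and adjusted p = 0.304 with an estimated correlation), and by -0.44 within the high spike-in class (adjusted p = 8.06e-11). AT5G48760 was at 257 ± 78.8 (SD, n = 3) against 727 ± 160 (n = 12). Cell division genes were lower in 8 of 20 cases and higher in 0, by a mean of -0.72 (adjusted p = 1.5e-05, and adjusted p = 0.304 with an estimated correlation), and by -0.47 within the high class (adjusted p = 0.00052). 3xHMG-box2, which binds mitotic chromosomes, was at 72.3 ± 6.44 against 202 ± 38.1. For the 13 replication and histone genes, 3 were lower and 0 higher, with a mean of -0.67 (adjusted p = 0.00735, and adjusted p = 0.304 with an estimated correlation) and -0.83 within the high class (adjusted p = 0.00172). ER body genes were lower in 4 of 7 cases and higher in 0, by a mean of -1.39 (adjusted p = 0.000193, and adjusted p = 0.112 with an estimated correlation), and by -1.14 within the high class (adjusted p = 4.87e-05). PYK10 was at 671 ± 133 against 3267 ± 2210. Touch, wound and elicitor genes were lower in 5 of 17 cases and higher in 1, by a mean of -0.59 (adjusted p = 0.0107, and adjusted p = 0.498 with an estimated correlation), and by -0.50 within the high class (adjusted p = 0.0124). Root cap genes were lower in 4 of 8 cases and higher in 0, by a mean of -1.65 (adjusted p = 0.000622, and adjusted p = 0.306 with an estimated correlation), with a mean of 0.02 and no call within the high class (adjusted p = 0.569).

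Heat shock genes were higher in SCR in 12 of 13 cases, by a mean log2 difference of 2.34 (adjusted p = 2.64e-08, and adjusted p = 0.304 with an estimated correlation). The list mean was 6.23 on SCR replicate 1, 9.79 on replicate 2 and 9.98 on replicate 3, against 5.14 to 7.53 on the arrays of the other lines, and the SCR difference within the high class was -0.10 (adjusted p = 0.441). HSA32 had signals of 68.3, 476 and 456 on the 3 SCR arrays. Its log2 difference within the high class was 0.40 (adjusted p = 0.642). Genes encoded in organelles also differed between the SCR arrays. For 54 plastid-encoded genes, 5 were lower and 0 higher, with a mean of -0.88 (adjusted p = 1.15e-05, and adjusted p = 0.676 with an estimated correlation) that was 0.81 within the high class (adjusted p = 1.46e-06). For 15 mitochondrion-encoded genes, 2 were lower and 0 higher, with a mean of -0.78 (adjusted p = 0.00618, and adjusted p = 0.592 with an estimated correlation). That mean was 0.29 within the high class (adjusted p = 0.569), and the call was lost without SCR replicate 3 (adjusted p = 0.0621).

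In all, limma called 3974 probe sets in SCR, 1732 higher and 2242 lower. Within the high spike-in class it called 389, 149 higher and 240 lower, and with the spike-in class as a block it called 405. The count was 1750 without SCR replicate 2 and 1800 without replicate 3, and 5095 without replicate 1. Replicate 1, the only SCR array of the high class, also stood apart in genes of other tissues, so the shifts within that class cannot be put down to the spike-in class alone. Of the root cap genes, sks15 was at 338, 46.5 and 43.9 on SCR replicates 1, 2 and 3, AT4G27400 at 275, 21.8 and 18.3, and AT1G65570 at 83.8, 2.01 and 0.742. The root hair mean was 6.23 on replicate 1 against 4.44 and 4.53 on the others. Its mean correlation with its own group (0.889) was the lowest of all 27 arrays. SCR is also the only Landsberg line, so cell type, background, spike-in class and this difference between arrays coincide in the group.

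**Figure D2:**
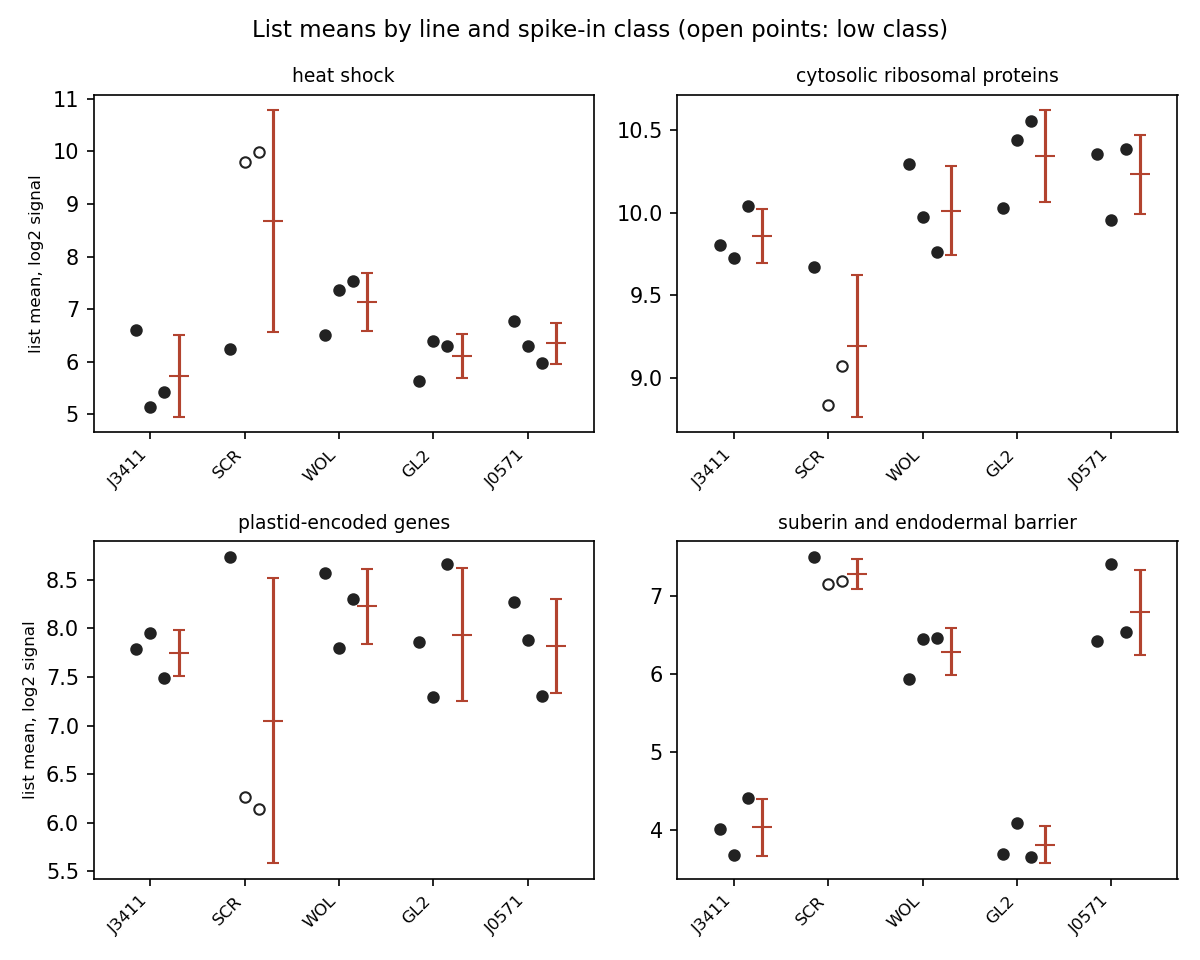
Mean log2 signal of 4 gene lists (y axis) on each of the 15 arrays of the marker lines (x axis), with filled points for the high spike-in class, open points for the low class, and the mean and SD of each line in red. Heat shock genes reach 9.79 and 9.98 on the open SCR points and 6.23 on the filled one, while suberin and endodermal barrier genes are high on all 3.

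WOL was set against the other lines for genes of the stele. Xylem wall genes and vascular regulators were higher in WOL, and so were root hair genes and class III peroxidases. In each of these lists only part of the genes passed, and their list calls were lost with an estimated correlation (adjusted p = 0.183 for xylem and 0.322 for the others). AT1G62480 ranked first by fitted log2 gain, with a signal of 2725 ± 306 (SD, n = 3) against 189 ± 371 (n = 12). AT4G11210 followed at 1126 ± 207 against 34.7 ± 41.3, and AT3G18280 at 1175 ± 166 against 97.3 ± 158. AT5G19100 had the first rank by fitted log2 loss, at 47.7 ± 13.4 against 530 ± 552.

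Of 13 genes for the secondary wall of the xylem, 7 were higher in WOL and 0 lower, by a mean log2 difference of 1.42 (adjusted p = 4.58e-08, and adjusted p = 0.183 with an estimated correlation). The peroxidase gene AT5G51890 of this list was at 227 ± 62.9 (SD, n = 3) against 21.9 ± 12.5 (n = 12), and IRX15, needed for xylan synthesis, at 16.9 ± 2.52 against 2.98 ± 1.80. Of 12 vascular and stele regulators, 4 were higher and 0 lower, by a mean of 0.86 (adjusted p = 0.00128, and adjusted p = 0.322 with an estimated correlation). PHV, a class III HD-ZIP transcription factor of vascular patterning, was at 115 ± 18.6 against 17.8 ± 5.73, and LBD16, a regulator of lateral root initiation, at 169 ± 32.5 against 109 ± 132. LBD16 was higher still on the 3 SCR arrays, at 212, 365 and 367.

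Root hair genes were higher in WOL in 11 of 15 cases and lower in 0, by a mean log2 difference of 2.21 (adjusted p = 2.18e-07, and adjusted p = 0.322 with an estimated correlation). The peroxidase gene AT3G49960 was at 156 ± 59.1 (SD, n = 3) against 21.9 ± 65.8 (n = 12). The mean log2 signal of the root hair list was 6.88, 7.14 and 7.55 on the 3 WOL arrays. It was also high on J3411 replicate 3 (7.52) and SCR replicate 1 (6.23), and 4.38 to 4.94 on every other array of the lines. For 55 class III peroxidases, 15 were higher and 0 lower, by a mean of 0.98 (adjusted p = 0.000123, and adjusted p = 0.322 with an estimated correlation), with AT3G21770 at 1018 ± 213 against 119 ± 105. Expansins and xyloglucan-modifying XTHs, enzymes and proteins that loosen cell walls, were higher in 5 of 11 cases and lower in 1, with the same counts adjusted over the list alone, by a mean of 0.87 (adjusted p = 0.0243, and adjusted p = 0.403 with an estimated correlation). XTH21 was at 396 ± 74.5 against 31.8 ± 32.0, and EXPA15 at 580 ± 207 against 120 ± 41.3. This list call was lost without SCR replicate 2 (adjusted p = 0.0825) and within the high spike-in class (adjusted p = 0.195).

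The remaining list calls in WOL were weaker. Extensins, the hydroxyproline-rich wall proteins, were higher in 2 of 11 cases and lower in 0, by a mean log2 difference of 0.96 (adjusted p = 0.0176, and adjusted p = 0.638 with an estimated correlation), and the call was lost without WOL replicate 2 (adjusted p = 0.154). Suberin and endodermal barrier genes were higher in 3 of 10 cases, by a mean of 0.80 (adjusted p = 0.0243, and adjusted p = 0.423 with an estimated correlation), lost without WOL replicate 2 or 3 (adjusted p up to 0.0826). Plastid-encoded genes had a mean of 0.59 with 0 of 54 past the threshold (adjusted p = 0.00986, and adjusted p = 0.906 with an estimated correlation), lost without WOL replicate 1 or 3 (adjusted p up to 0.137) and within the high class (adjusted p = 0.566). ER body genes were lower in 1 of 7 cases, by a mean of -0.37 (adjusted p = 0.0261, and adjusted p = 0.322 with an estimated correlation), lost without SCR replicate 1 or WOL replicate 1 or 2 (adjusted p up to 0.0851) and after quantile normalization (adjusted p = 0.209). Touch, wound and elicitor genes were lower in 1 of 17 cases, by a mean of -0.32 (adjusted p = 0.00986, and adjusted p = 0.468 with an estimated correlation), lost without WOL replicate 1 (adjusted p = 0.0851) and after quantile normalization (adjusted p = 0.139).

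In the auxin response list of 6 genes, 3 were higher in WOL and 0 lower, or 4 and 0 adjusted over the list alone, by a mean log2 difference of 0.88, and the list did not pass the set test (adjusted p = 0.051, and adjusted p = 0.322 with an estimated correlation). Its adjusted p was 0.0162 to 0.322 over the alternatives, with 0.0352 after quantile normalization and 0.032 within the high spike-in class. The cortex list had 1 gene lower and 0 higher in WOL, with a mean of 0.17, a median of 0.62 and a set test pointing down (adjusted p = 0.791).

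Across all probe sets limma called 1514 in WOL, 1199 higher and 315 lower, so that 79.2% of the calls were higher. The share was 65.1% after quantile normalization, which moved the median log2 difference of all probe sets from 0.09 to -0.07. Leaving out WOL replicate 1, 2 or 3 gave 826, 738 or 907 calls.

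**Figure D3:**
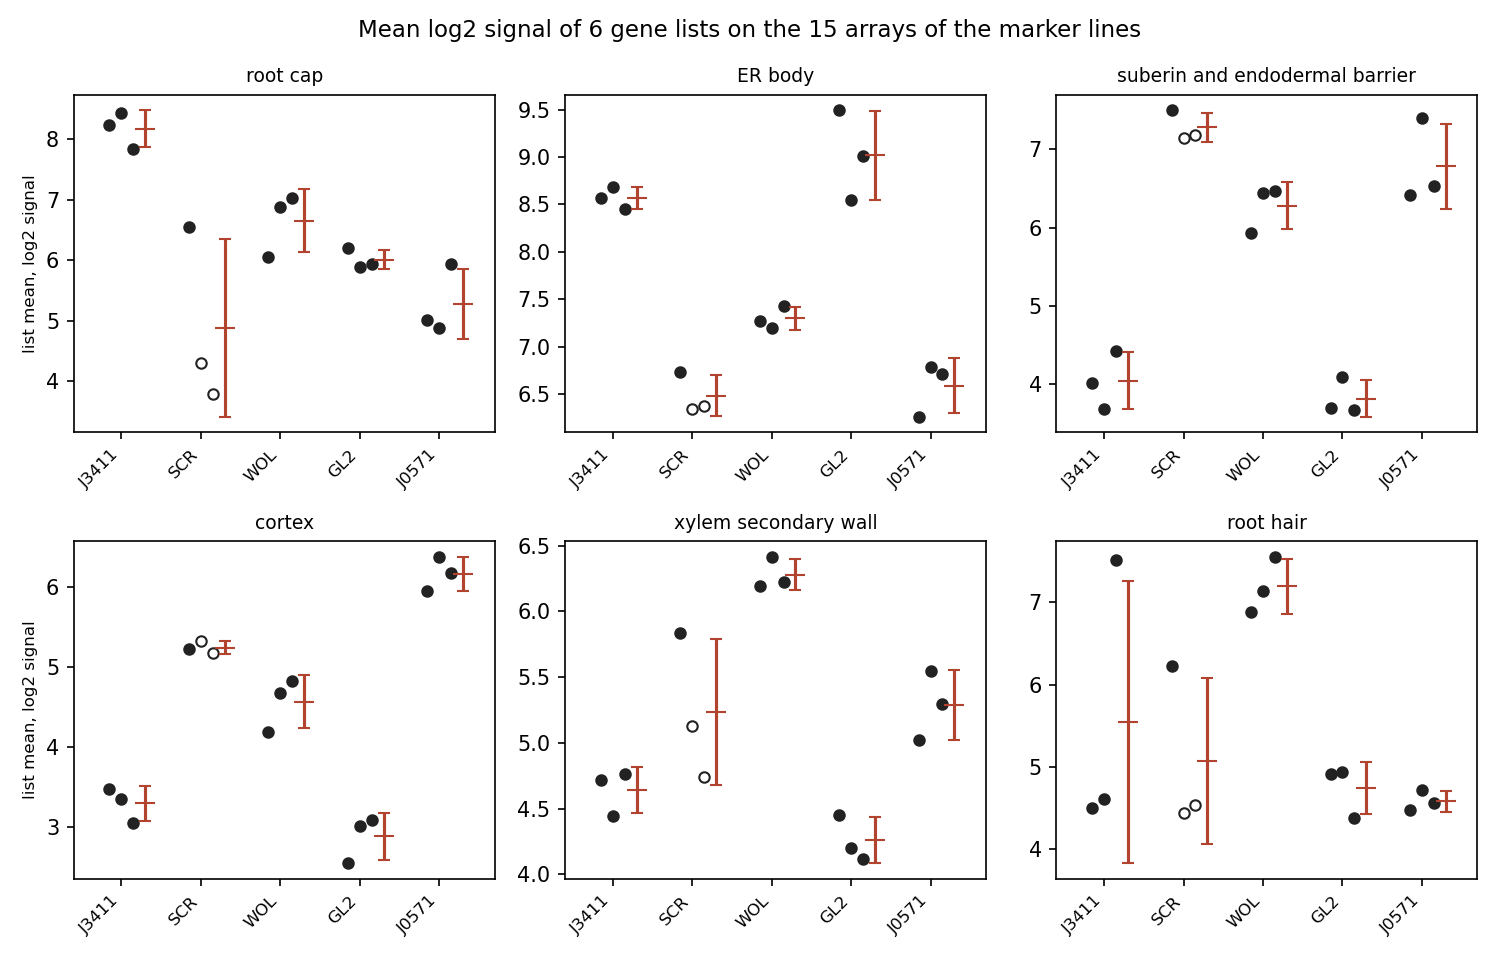
Mean log2 signal of 6 gene lists (y axis) on each of the 15 arrays of the marker lines (x axis), with filled points for the high spike-in class, open points for the low class, and the mean and SD of each line in red. Root cap genes are highest in J3411, suberin and endodermal barrier genes in SCR, cortex genes in J0571 and xylem genes in WOL, and root hair genes reach 7.52 on J3411 replicate 3.

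For the hairless epidermal cells, GL2 was compared with the other 4 lines. As lists, ER body genes were higher in GL2, and genes of the endodermal barrier, the cortex and the xylem wall were lower. In each list only part of the genes passed, and for the xylem wall a minority. Of these list calls, that of the xylem wall was lost with an estimated correlation (adjusted p = 0.28). AT2G25450 was first by fitted log2 gain, with a signal of 633 ± 183 (SD, n = 3) against 99.97 ± 153.1 (n = 12). AT5G43030 followed, at 151 ± 57.0 against 6.00 ± 10.6, at least 8.74-fold. AT5G35580 was first by fitted log2 loss, at 1.63 ± 0.803 against 236 ± 184 and at least 11.7-fold lower, followed by AT5G45210, at 1.42 ± 0.546 against 271 ± 271 and at least 5.81-fold lower. TRY, an R3 MYB protein of epidermal patterning, was the only gene measured of the non-hair epidermis list, at 79.9 ± 19.3 against 21.8 ± 15.1 (adjusted p = 0.00979), a call lost without GL2 replicate 3 (adjusted p = 0.0701).

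Of 7 ER body genes, 6 were higher in GL2 and 0 lower, by a mean log2 difference of 1.78 (adjusted p = 2.11e-08, and adjusted p = 0.0165 with an estimated correlation). NAI2, an ER body component, was at 2499 ± 184 (SD, n = 3) against 535 ± 538 (n = 12), PYK10 at 5795 ± 1189 against 1986 ± 1714, and NAI1 at 424 ± 122 against 187 ± 155. Suberin and endodermal barrier genes were lower in 6 of 10 cases and higher in 0, by a mean of -2.28 (adjusted p = 1.07e-07, and adjusted p = 0.0459 with an estimated correlation), with AT4G11290 at 5.74 ± 2.28 against 1251 ± 1153, at least 24.6-fold lower, and GSO1 at 24.5 ± 7.07 against 497 ± 464. In the cortex list 4 of 5 genes were lower and 0 higher, or 5 lower adjusted over the list alone, by a mean of -1.94 (adjusted p = 7.82e-05, and adjusted p = 0.0165 with an estimated correlation). JKD was at 1.28 ± 0.382 against 36.4 ± 35.5. Xylem wall genes were lower in 4 of 13 cases and higher in 0, by a mean of -1.10 (adjusted p = 0.000853, and adjusted p = 0.28 with an estimated correlation).

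Beta-glucosidase genes went both ways in GL2, with 7 of 20 lower and 2 higher and a mean log2 difference of -0.80 (adjusted p = 0.0218, and adjusted p = 0.0884 with an estimated correlation). BGLU46 was at 31.3 ± 11.2 (SD, n = 3) against 159 ± 111 (n = 12), while PYK10, a beta-glucosidase too, was among the higher genes. Replication and histone genes were higher in 2 of 13 cases and lower in 0, by a mean of 0.73 (adjusted p = 0.000713, and adjusted p = 0.172 with an estimated correlation), with the histone H2B gene HTB2 at 400.3 ± 120 against 143 ± 85.9. Ribosomal protein genes were higher in 13 of 121 cases and lower in 0, by a mean of 0.52 against a comparison that includes SCR (adjusted p = 3.08e-16, and adjusted p = 0.574 with an estimated correlation). Class III peroxidases were lower in 15 of 55 cases and higher in 7, by a mean of -0.69 (adjusted p = 0.0267, and adjusted p = 0.691 with an estimated correlation), and the call was lost without J3411 replicate 3, SCR replicate 1 or GL2 replicate 3 (adjusted p up to 0.0647). Prx37 was at 6.29 ± 5.28 against 468 ± 441, at least 13.7-fold lower. Root hair genes were lower in 2 of 15 cases and higher in 0, by a mean of -0.85 (adjusted p = 0.0279, and adjusted p = 0.742 with an estimated correlation), lost without SCR replicate 1 or GL2 replicate 3 (adjusted p up to 0.138). The comparison includes WOL (6.88 to 7.55), J3411 replicate 3 (7.52) and SCR replicate 1 (6.23), where this list was high. On the GL2 arrays the list mean was 4.38 to 4.94, much as on the J0571 arrays (4.47 to 4.72). Mitochondrion-encoded genes had a mean of 0.45 with 0 of 15 past the threshold (adjusted p = 0.0279, and adjusted p = 0.753 with an estimated correlation), a call lost without SCR replicate 2, GL2 replicate 3 or J0571 replicate 3 (adjusted p up to 0.531), after quantile normalization (adjusted p = 0.0751) and within the high class (adjusted p = 0.236).

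The total for GL2 was 2908 probe sets by limma, 1159 higher and 1749 lower. Without GL2 replicate 2 it was 1874, and without replicate 3 it was 1605. Quantile normalization gave 1237 higher and 1337 lower, so that the share of higher calls went from 39.9% to 48.1%, and moved the median log2 difference of all probe sets in GL2 from -0.09 to 0.04. Most of the excess of lower calls at the adjusted p threshold was thus lost after quantile normalization. On the deposited scale, calls of at least 2-fold were 696 higher and 1373 lower. Among Columbia lines only, calls were 981 higher and 1768 lower. The 2-fold calls were not counted after quantile normalization, so how far their excess depends on the scaling was not tested.

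J0571 was compared with the other 4 lines for genes of the ground tissue and quiescent centre. Cortex genes and endodermal barrier genes were higher in J0571, and ER body genes were lower. Of these list calls, that of barrier genes was lost with an estimated correlation (adjusted p = 0.125). AT2G15560 ranked first by fitted log2 change, with a signal of 704 ± 124 (SD, n = 3) against 40.4 ± 54.0 (n = 12), followed by AT5G45210 (611 ± 130 against 118 ± 182) and AT1G62500, the cortex marker CO2 (419 ± 294 against 15.6 ± 5.93, at least 18.4-fold). AT5G04970 was first by fitted log2 loss, at 1.56 ± 0.794 against 77.9 ± 60.8 and at least 3.34-fold lower, followed by the glutathione transferase gene GSTU25, at 122 ± 17.1 against 1153 ± 735.

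In the cortex list 3 of 5 genes were higher in J0571 and 0 lower, or 4 and 0 adjusted over the list alone, by a mean log2 difference of 2.18 (adjusted p = 3.32e-07, and adjusted p = 0.00617 with an estimated correlation). Beside AT1G62500, these were AT1G09750, at 209 ± 62.5 (SD, n = 3) against 41.6 ± 43.8 (n = 12), and JKD, at 87.3 ± 31.9 against 14.9 ± 14.2. Suberin and endodermal barrier genes were higher in 5 of 10 cases and lower in 0, by a mean of 1.43 (adjusted p = 1.34e-05, and adjusted p = 0.125 with an estimated correlation), with AT1G44970, a class III peroxidase, at 1669 ± 923 against 397 ± 517. ER body genes were lower in 5 of 7 cases and higher in 0, by a mean of -1.26 (adjusted p = 1.16e-07, and adjusted p = 0.0121 with an estimated correlation), with NAI2 at 123 ± 18.21 against 1129 ± 958. Root cap genes were lower in 1 of 8 cases, by a mean of -1.15 (adjusted p = 0.000231, and adjusted p = 0.503 with an estimated correlation).

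Smaller shifts in J0571 covered tubulins (1 of 7 higher, mean log2 difference 0.53, adjusted p = 0.00441, and adjusted p = 0.602 with an estimated correlation), with TUB5 at 663 ± 16.9 (SD, n = 3) against 308 ± 136 (n = 12). Ribosomal protein genes had 3 of 121 higher and 1 lower, with a mean of 0.38 (adjusted p = 8.27e-10, and adjusted p = 0.69 with an estimated correlation). The number called was near the general share, 4.69% of all probe sets. Against the 3 lines other than SCR, where this list was low, the J0571 shift was 0.16, within the SD of the J0571 arrays (0.241). Root hair genes had a mean of -1.05 with 0 of 15 past the threshold (adjusted p = 0.00103, and adjusted p = 0.602 with an estimated correlation). That comparison includes WOL, where this list was high, and its mean on the J0571 arrays (4.47 to 4.72) was much as on the GL2 arrays (4.38 to 4.94). Serine carboxypeptidase-like genes had 1 of 29 lower and a mean of -0.34 (adjusted p = 0.00636, and adjusted p = 0.503 with an estimated correlation). For the 13 nuclear photosynthesis genes 0 passed, with a mean of 0.83 (adjusted p = 0.00353, and adjusted p = 0.602 with an estimated correlation), and the call was lost without J0571 replicate 3 (adjusted p = 0.804).

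Probe sets called by limma in J0571 numbered 1066, 555 higher and 511 lower. There were 408 without J0571 replicate 1 and 488 without replicate 3. J0571 had low actin 3' control signals, as J3411 did.

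J0571 against SCR addressed the cortex, which by the labels only J0571 marks of the pair. Background differs too, Columbia for J0571 and Landsberg for SCR, so the differences cannot be put down to the cortex alone. AT1G62500 (CO2) was higher in J0571, with a signal of 419 ± 294 (SD, n = 3) against 14.4 ± 2.21 (n = 3), at least 20.5-fold. The cortex list as a whole had 2 of 5 genes higher and 0 lower, or 3 higher and 1 lower adjusted over the list alone, and did not pass the set test (adjusted p = 0.125). AT2G15560 ranked first by fitted log2 gain, at 704 ± 124 against 70.5 ± 116, but its signals on the SCR arrays were 205, 4.25 and 2.29, and within the high spike-in class its log2 difference was 1.75 (adjusted p = 0.0728). AT4G29200 came next, at 628.8 ± 94.95 against 17.3 ± 4.36, with a log2 difference of 4.72 within the high class. Its signal was about as high in J3411, whose label names no cortex. AT2G19310 was first by fitted log2 loss, at 11.7 ± 7.25 against 288 ± 284, with -1.70 within the high class (adjusted p = 0.233).

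Ribosomal protein genes were higher in J0571 than in SCR in 56 of 121 cases and lower in 1, by a mean log2 difference of 1.04 (adjusted p = 1.45e-29, and adjusted p = 0.434 with an estimated correlation), and by 0.56 within the high class (adjusted p = 7.41e-13). AT5G48760 was at 885 ± 131 (SD, n = 3) against 257 ± 78.8 (n = 3). Cell division genes were higher in 4 of 20 cases, by a mean of 0.77 (adjusted p = 2.51e-05, and adjusted p = 0.434 with an estimated correlation), and by 0.52 within the high class (adjusted p = 0.00132), with 3xHMG-box2 at 208 ± 27.3 against 72.3 ± 6.44. Replication and histone genes were higher in 1 of 13 cases, by a mean of 0.65 (adjusted p = 0.0124, and adjusted p = 0.434 with an estimated correlation), and by 0.81 within the high class (adjusted p = 0.00669). UDP-glycosyltransferase genes were lower in 9 of 47 cases, by a mean of -0.58 (adjusted p = 0.000374, and adjusted p = 0.434 with an estimated correlation), and by -0.40 within the high class (adjusted p = 0.229), with UGT87A2 at 40.6 ± 12.3 against 271 ± 90.8.

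Heat shock genes were lower in J0571 than in SCR in 4 of 13 cases, by a mean log2 difference of -2.32 (adjusted p = 3.87e-07, and adjusted p = 0.496 with an estimated correlation), but by the high class alone the mean was 0.12 (adjusted p = 0.417). Plastid-encoded genes had 0 of 54 past the threshold and a mean of 0.77 (adjusted p = 0.000594, and adjusted p = 0.839 with an estimated correlation), against -0.92 within the high class (adjusted p = 1.58e-06), and the call was lost without SCR replicate 2 or 3 (adjusted p up to 0.159). For this pair limma called 2036 probe sets, 1284 higher and 752 lower, but 344 within the high class and 377 with the class as a block. The count was 3333 without SCR replicate 1, 869 without SCR replicate 2, 902 without SCR replicate 3, 475 without J0571 replicate 1 and 586 without J0571 replicate 3.

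GL2 against J3411 set hairless epidermal cells against epidermis with lateral root cap. Root cap genes were lower in GL2 in 5 of 8 cases and higher in 0, by a mean log2 difference of -2.16 (adjusted p = 0.000171, and adjusted p = 0.555 with an estimated correlation). AT4G27400 was at 86.2 ± 23.4 (SD, n = 3) against 1575 ± 697 (n = 3) and AT4G18425 at 19.3 ± 4.12 against 90.5 ± 21.3. First by fitted log2 gain was AT2G25450, at 633 ± 183 against 1.78 ± 0.749 and at least 41.7-fold higher, followed by AT5G43030, at least 9.70-fold higher. AT4G39675 ranked first by fitted log2 loss, at 5.36 ± 5.47 against 1030 ± 812 and at least 40.5-fold lower, followed by AT4G29200, at 11.0 ± 9.83 against 636 ± 75.1 and at least 37.7-fold lower.

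Touch, wound and elicitor genes were lower in GL2 than in J3411 in 2 of 17 cases, by a mean log2 difference of -0.79 (adjusted p = 0.00466, and adjusted p = 0.729 with an estimated correlation). Expansins and XTHs were lower in 1 of 11 cases, or 2 adjusted over the list alone, by a mean of -0.76 (adjusted p = 0.0227, and adjusted p = 0.555 with an estimated correlation), with EXGT-A3 at 26.2 ± 7.49 (SD, n = 3) against 177 ± 72.8 (n = 3). Replication and histone genes were higher in 2 of 13 cases, by a mean of 0.89 (adjusted p = 0.000108, and adjusted p = 0.236 with an estimated correlation). Ribosomal protein genes were higher in 5 of 121 cases and lower in 1, by a mean of 0.48 (adjusted p = 6.1e-11, and adjusted p = 0.91 with an estimated correlation). Beta-glucosidase genes were lower in 2 of 20 cases and higher in 1, by a mean of -0.69 (adjusted p = 0.0405, and adjusted p = 0.236 with an estimated correlation) or -1.04 with no pseudocount, a call lost without J3411 replicate 1 or 3 or GL2 replicate 1 or 3 (adjusted p up to 0.119). By limma 1222 probe sets differed between GL2 and J3411, 520 higher and 702 lower. There were 403, 442 or 2428 without J3411 replicate 1, 2 or 3, and 673 or 620 without GL2 replicate 2 or 3. Background differs between these lines as well as cell type.

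The stages follow cells from division to elongation to maturity, and Stage II against Stage I covers the start of elongation. Cell division genes fell and tubulin genes rose at this step, and cortex genes were higher in Stage II. With an estimated correlation these list calls were lost (adjusted p = 0.0842, 0.221 and 0.227). AT1G04040 ranked first by fitted log2 rise, from a signal of 18.0 ± 16.9 (SD, n = 4) to 1562 ± 501 (n = 4), at least 75.9-fold, followed by AT1G62480 (14.2 ± 8.58 to 598 ± 222, at least 32.5-fold) and AT4G11290 (7.55 ± 9.75 to 310 ± 225, at least 14.7-fold). AT1G50060 ranked first by fitted log2 fall, from 1946 ± 644 to 47.5 ± 57.8. Next was GH9B6, of the glycosyl hydrolase family 9 of endoglucanases, from 285 ± 80.0 to 2.96 ± 0.562 and at least 18.7-fold.

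Of 20 cell division genes, 19 fell and 0 rose from Stage I to Stage II, by a mean log2 difference of -1.49 (adjusted p = 1.08e-12, and adjusted p = 0.0842 with an estimated correlation). This mean was -1.64 within the high spike-in class and -1.35 within the low class. The Aurora kinase gene AUR2 fell from 198 ± 30.4 (SD, n = 4) to 48.7 ± 9.91 (n = 4), and the spindle checkpoint gene BUB3.1 from 322 ± 46.8 to 102 ± 6.10. Of 7 tubulins, 4 rose and 0 fell, by a mean of 1.25 (adjusted p = 0.000862, and adjusted p = 0.221 with an estimated correlation), with 1.28 in the high class and 1.22 in the low class. TUB1 rose from 59.1 ± 8.40 to 1095 ± 299 and TUB5 from 102 ± 30.5 to 695 ± 112. In the cortex list 3 of 5 genes rose and 0 fell, or 3 and 1 adjusted over the list alone, by a mean of 1.77 (adjusted p = 0.0209, and adjusted p = 0.227 with an estimated correlation). AT1G09750 rose from 18.7 ± 3.82 to 278 ± 107. The cortex call was lost within the low class (adjusted p = 0.0504) and without Stage II replicate 4 (adjusted p = 0.0605).

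Root cap genes fell in 4 of 8 cases from Stage I to Stage II and rose in 0, by a mean log2 difference of -1.61 (adjusted p = 0.0209, and adjusted p = 0.221 with an estimated correlation). AT1G65570 fell from 560 ± 196 (SD, n = 4) to 20.5 ± 11.1 (n = 4), and the list call was lost without Stage I replicate 2 (adjusted p = 0.0645). Ribosomal protein genes fell in 16 of 121 cases, by a mean of -0.45 (adjusted p = 5.78e-06, and adjusted p = 0.709 with an estimated correlation), and by -0.28 within the low spike-in class. BBM, an AP2-type transcription factor of the stem cell niche, fell from 52.2 ± 23.8 to 5.18 ± 1.80 (adjusted p = 0.000469). In total limma called 4564 probe sets, 2044 higher and 2520 lower in Stage II, with 2797 within the high spike-in class, 2689 within the low class and 5921 with the class as a block.

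**Figure D4:**
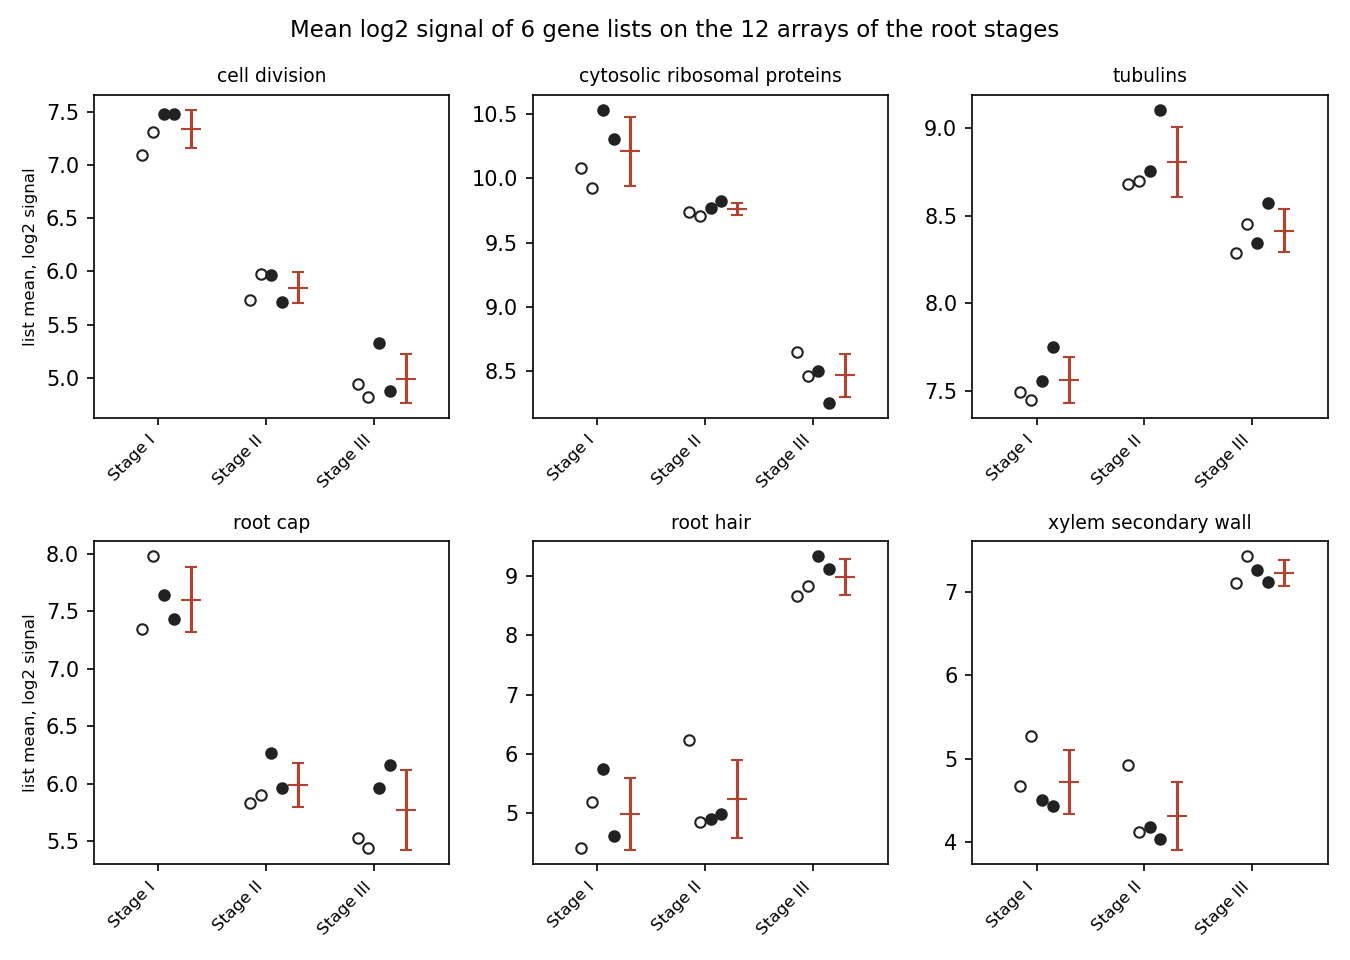
Mean log2 signal of 6 gene lists (y axis) on each of the 12 stage arrays (x axis, stages in order of distance from the tip), with filled points for the high spike-in class, open points for the low class, and the mean and SD of each stage in red. Cell division and root cap genes fall after Stage I, tubulins rise in Stage II (their lower mean in Stage III did not pass, adjusted p = 0.0533), and root hair and xylem genes are highest in Stage III.

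Stage III against Stage II covers the step to mature tissue. Root hair, extensin, peroxidase, xylem wall and endodermal barrier genes rose, and ribosomal protein, histone and cell division genes fell. With an estimated correlation these list calls were lost (adjusted p = 0.0511 to 0.14), and 23 of 55 peroxidases and 5 of 10 barrier genes were among those that rose. The peroxidase gene AT5G66390 ranked first by fitted log2 rise, from a signal of 11.2 ± 17.5 (SD, n = 4) to 1058 ± 351 (n = 4), at least 54.1-fold, followed by AT4G13580, whose lower bound of 66.2-fold is higher, and the peroxidase gene AT3G49960, at least 37.0-fold. AT1G13730 ranked first by fitted log2 fall, from 217 ± 46.2 to 30.6 ± 29.1, followed by AT2G20480, from 38.9 ± 3.07 to 1.99 ± 0.641 and at least 2.62-fold.

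All 15 root hair genes measured rose from Stage II to Stage III, by a mean log2 difference of 3.75 (adjusted p = 4.04e-13, and adjusted p = 0.074 with an estimated correlation), 4.29 within the high spike-in class and 3.21 within the low class. EXPA18, an expansin of root hair initiation, rose from 61.3 ± 50.7 (SD, n = 4) to 1839 ± 640 (n = 4). Stage II replicate 1 had a root hair list mean of 6.23, against 4.86 to 4.98 on the other Stage II arrays. Of 11 extensins, 8 rose and 0 fell, by a mean of 2.47 (adjusted p = 3.4e-07, and adjusted p = 0.0827 with an estimated correlation), with AT4G08410 from 32.3 ± 9.59 to 414 ± 225. Class III peroxidases rose in 23 of 55 cases and fell in 3, by a mean of 1.57 (adjusted p = 1.4e-05, and adjusted p = 0.084 with an estimated correlation). Xylem wall genes rose in 11 of 13 cases and fell in 0, by a mean of 2.91 (adjusted p = 4.24e-09, and adjusted p = 0.0511 with an estimated correlation), 3.08 within the high class and 2.75 within the low class. GUT2, a xylan synthesis gene, rose from 39.9 ± 5.03 to 190 ± 23.5 and AT5G51890 from 41.1 ± 26.1 to 721 ± 94.3.

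Suberin and endodermal barrier genes rose in 5 of 10 cases from Stage II to Stage III and fell in 0, by a mean log2 difference of 2.28 (adjusted p = 2e-04, and adjusted p = 0.14 with an estimated correlation). GSO1 rose from 54.8 ± 20.15 (SD, n = 4) to 516 ± 38.6 (n = 4). Vascular and stele regulators rose in 5 of 12 cases and fell in 1, by a mean of 0.89 (adjusted p = 0.0169, and adjusted p = 0.16 with an estimated correlation), a call lost within the high class (adjusted p = 0.123). Among them SWEET11, a sucrose transporter of the phloem, rose from 33.6 ± 3.74 to 232 ± 88.2, and LBD16 from 16.8 ± 3.77 to 90.5 ± 18.5. Iron and zinc genes rose in 5 of 11 cases, by a mean of 0.72 (adjusted p = 0.00855, and adjusted p = 0.074 with an estimated correlation), with the zinc deficiency regulator bZIP19 from 138 ± 47.5 to 379 ± 75.2. Touch, wound and elicitor genes rose in 8 of 17 cases, by a mean of 0.86 (adjusted p = 0.00147, and adjusted p = 0.221 with an estimated correlation). Nuclear photosynthesis genes rose in 6 of 13 cases, by a mean of 1.05 (adjusted p = 0.00596, and adjusted p = 0.137 with an estimated correlation).

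In 3 other families the share of genes past the test was below the 30.9% of all probe sets. UDP-glycosyltransferase genes rose in 9 of 47 cases and fell in 2, by a mean log2 difference of 0.56 (adjusted p = 0.0198, and adjusted p = 0.084 with an estimated correlation), a call lost within the high class (adjusted p = 0.0843). Tau glutathione transferases rose in 2 of 11 cases, by a mean of 0.87 (adjusted p = 0.0324, and adjusted p = 0.14 with an estimated correlation), with GSTU28 from 37.8 ± 19.6 (SD, n = 4) in Stage II to 429 ± 147 (n = 4) in Stage III. SWEET transporters rose in 3 of 14 cases, by a mean of 0.70 (adjusted p = 0.0375, and adjusted p = 0.191 with an estimated correlation), lost without Stage II replicate 3 or 4 or Stage III replicate 1 or 2 (adjusted p up to 0.0723), within the high class (adjusted p = 0.0843) and after quantile normalization (adjusted p = 0.0837). Expansins and XTHs rose in 6 of 11 cases and fell in 2, with the same counts adjusted over the list alone, by a mean of 0.90 (adjusted p = 0.0449, and adjusted p = 0.164 with an estimated correlation). EXGT-A3 rose from 162 ± 37.0 to 525 ± 127. The expansin list lost its call without Stage II replicate 4 (adjusted p = 0.0832) or Stage III replicate 2 (adjusted p = 0.0738). It also lost it with no pseudocount (adjusted p = 0.0536), within the high class (adjusted p = 0.0843), within the low class (adjusted p = 0.182) with the spike-in class as a block (adjusted p = 0.119) and with the replicate block (adjusted p = 0.125).

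Ribosomal protein genes fell in 103 of 121 cases from Stage II to Stage III and rose in 0, by a mean log2 difference of -1.29 (adjusted p = 4.82e-33, and adjusted p = 0.074 with an estimated correlation), -1.42 within the high class and -1.17 within the low class. AT5G28060 fell from 391 ± 57.7 (SD, n = 4) to 99.6 ± 21.4 (n = 4). Replication and histone genes fell in 9 of 13 cases, by a mean of -1.13 (adjusted p = 7.08e-07, and adjusted p = 0.0511 with an estimated correlation), with HTB4 from 864 ± 88.0 to 319 ± 36.1. Cell division genes fell in 12 of 20 cases, by a mean of -0.86 (adjusted p = 1.56e-05, and adjusted p = 0.114 with an estimated correlation). The limma count was 7038, with 3585 higher and 3453 lower in Stage III. The balance was 3141 higher and 4282 lower after quantile normalization, and 2877 and 1919 with calls of at least 2-fold. It was 5807 within the high spike-in class, 4532 within the low class and 8270 with the class as a block. Quantile normalization moved the median log2 difference of all probe sets from 0.08 to -0.11.

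Stage III against Stage I spans the whole series from dividing to mature cells. AT1G04040 ranked first by fitted log2 rise, from a signal of 18.0 ± 16.9 (SD, n = 4) to 2767 ± 2071 (n = 4), at least 110.2-fold, followed by the extensin gene AT3G28550, from 1.57 ± 0.586 to 566 ± 244 and at least 35.2-fold. AT1G50060 ranked first by fitted log2 fall, from 1946 ± 644 to 68.4 ± 91.4, followed by AT5G24070, from 220.1 ± 57.5 to 4.197 ± 5.42 and at least 14.6-fold. Of 20 cell division genes 19 fell and 0 rose, by a mean log2 difference of -2.35 (adjusted p = 3.69e-12, and adjusted p = 0.0646 with an estimated correlation). 3xHMG-box2 fell from 558 ± 129 to 40.7 ± 16.2 and TOPII, the gene of topoisomerase II, from 471 ± 60.9 to 39.6 ± 22.4. Ribosomal protein genes fell in 111 of 121 cases, by a mean of -1.74 (adjusted p = 1.33e-28, and adjusted p = 0.0714 with an estimated correlation), and replication and histone genes in 11 of 13 cases, by -1.34 (adjusted p = 1.19e-05, and adjusted p = 0.0646 with an estimated correlation).

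All 15 root hair genes rose from Stage I to Stage III, by a mean log2 difference of 4.00 (adjusted p = 3.85e-11, and adjusted p = 0.0715 with an estimated correlation). Extensins rose in 8 of 11 cases, by a mean of 2.73 (adjusted p = 1.16e-05, and adjusted p = 0.106 with an estimated correlation), and peroxidases in 27 of 55 cases with 2 falling, by 1.85 (adjusted p = 2.19e-06, and adjusted p = 0.0715 with an estimated correlation). Xylem wall genes rose in 10 of 13 cases, by 2.51 (adjusted p = 2.19e-06, and adjusted p = 0.0714 with an estimated correlation), and suberin and endodermal barrier genes in 5 of 10 cases, by 2.61 (adjusted p = 0.00147, and adjusted p = 0.196 with an estimated correlation). Expansins and XTHs rose in 7 of 11 cases and fell in 3, with the same counts adjusted over the list alone, by a mean of 1.55 (adjusted p = 0.0311, and adjusted p = 0.152 with an estimated correlation). That call was lost within the high class (adjusted p = 0.0712), within the low class (adjusted p = 0.0705), with the class as a block (adjusted p = 0.0786) and with the replicate block (adjusted p = 0.0776). The cortex list had 3 of 5 genes higher and 0 lower, or 3 and 1 adjusted over the list alone, and did not pass the set test (adjusted p = 0.0748). Its member AT1G62510 rose from 5.22 ± 5.00 (SD, n = 4) to 776 ± 482 (n = 4), at least 42.5-fold.

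Root cap genes fell in 5 of 8 cases from Stage I to Stage III and rose in 1, by a mean log2 difference of -1.83 (adjusted p = 0.0412, and adjusted p = 0.152 with an estimated correlation). AT4G18425 was the gene that rose, from 26.9 ± 14.4 (SD, n = 4) to 323 ± 30.1 (n = 4). The root cap call was lost without Stage I replicate 2 or 3 or Stage III replicate 3 (adjusted p up to 0.0844) and after quantile normalization (adjusted p = 0.0677). UDP-glycosyltransferase genes rose in 18 of 47 cases and fell in 4, by a mean of 0.72 (adjusted p = 0.00787, and adjusted p = 0.0714 with an estimated correlation), with UGT71C1 from 10.8 ± 5.67 to 301 ± 107. Iron and zinc genes rose in 6 of 11 cases, by 0.79 (adjusted p = 0.0211, and adjusted p = 0.0762 with an estimated correlation), touch, wound and elicitor genes in 9 of 17 cases, by 0.82 (adjusted p = 0.00825, and adjusted p = 0.306 with an estimated correlation), and tau glutathione transferases in 4 of 11 cases, by 1.21 (adjusted p = 0.0309, and adjusted p = 0.143 with an estimated correlation). SWEET transporters rose in 5 of 14 cases, by 0.78 (adjusted p = 0.0318, and adjusted p = 0.196 with an estimated correlation), lost without Stage I replicate 4 or Stage III replicate 1 (adjusted p up to 0.057), within the high class (adjusted p = 0.0612) and after quantile normalization (adjusted p = 0.0653). In this pair limma called 9806 probe sets, 43.1% of those tested, with 4779 higher and 5027 lower in Stage III. List counts such as those of SWEET transporters and tau glutathione transferases should be read beside that share. The count was 8229 within the high class, 8139 within the low class and 10805 with the class as a block. Quantile normalization moved the median log2 difference of all probe sets from 0.07 to -0.05.

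The lists of CYP71B cytochromes (19 measured) and AGAMOUS-like genes (40 measured) passed the set test in 0 of the 10 comparisons, and so did the auxin response list.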

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

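In this part, the tests for RNA degradation, for the endodermis, for Landsberg sequence and for probe sets 2-fold below all other arrays, and the comparison with an equal fold in all genes, were chosen only after the result was seen.

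In groups of 4 arrays, 20 of 191 groups tested (10.5%) had 1 array far from the other 3, where chance gives about 1 in 20. Many of these values share an array, so they are not independent. Stage I replicate 4 had a mean correlation of 0.927 with its own group, against 0.941 to 0.943 for the others. Stage II replicate 1 had list means (log2) of 6.227 for root hair, 4.918 for xylem secondary wall, 5.669 for touch, wound and elicitor genes and 6.202 for tau glutathione transferases. The highest of the other Stage II arrays were at 4.983, 4.181, 4.851 and 5.773. The signals of Stage II replicate 1 were 37.33 for AT5G66390, 56.98 for AT4G13580, 30.12 for AT3G49960, 136.6 for EXPA18, 44 for AT1G44970 and 68.91 for AT2G39430. The highest of the other Stage II arrays were at 4.333, 7.341, 2.902, 45.99, 19.72 and 24.73. No explanation was tested for that array.

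The remaining arrays far from their group were in single genes or 1 list. In Stage II, AT1G50060 was at 133.5 and AT1G65570 at 37.02 on replicate 3, and TUB1 at 1540 on replicate 4. In Stage I, AT1G80750 was at 852.9 on replicate 3. In Stage III, AT5G24070 was at 12.29 on replicate 3, GSO1 at 573.5 and the tau glutathione transferase mean at 6.877 on replicate 4, and SWEET11 at 363.9 and bZIP19 at 490.2 on replicate 2.

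J3411 and J0571 shared low actin 3' control signals and a high AT4G29200, at 636 and 628.8 against 17.3 in SCR and 11.0 in GL2, values chosen after they were seen. RNA degradation shared by both lines is argued against, since 5 of their 6 arrays had a GAPDH 3'/5' ratio inside the range of WOL and GL2. Their actin 3'/5' ratios (0.660 to 1.15) lay below those of WOL and GL2 (6.61 to 11.2), where degradation raises the ratio. The actin 5' signals were similar, at 118 to 225 in J3411 and J0571 and 94.7 to 312 in WOL and GL2. The low actin ratio therefore restates the low actin 3' signal and is not separate evidence. Probe sets low in a single line at one eighth of all other arrays numbered 0 for the smaller of J3411 and SCR and 0 at most among Columbia lines, with 0 for J3411 and J0571 together and 1 for the larger pair sharing a cell type, too few to decide. At 2-fold below, J3411 had 8 and SCR 3, against 1 in WOL, 3 in J0571 and 15 in GL2, the only Columbia line above both, which was written down as counting against sequence but rests on 1 line whose low probe sets were not explained by any test. J3411 and J0571 together had 7 and J3411 with GL2 had 23, while every other pair of lines had 0. By the labels J3411 and GL2 share the epidermis, but J3411 and J0571 share no cell type. A cell type named by both labels therefore cannot account for the 7, and these counts do not decide whether shared background sequence does. If the Columbia label of J0571 were wrong, the comparisons among Columbia lines would be affected.

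Heat shock genes were higher and ribosomal protein genes lower in SCR, mainly on replicates 2 and 3. The array class is argued against as the whole source, since on the stage arrays the low class differed from the high class by 0.292 for heat shock (SD 0.123 over stages) and -0.103 for ribosomal genes (SD 0.30), against SCR shifts of 2.34 and -0.919. Landsberg sequence is argued against for heat shock, since a mismatch dims a probe set, while the median log2 change of this list was 2.48. That follows from the direction of the pattern and is not a separate test. Of ribosomal genes 75.2% were lower, against 9.86% of all probe sets. The list was followed up because it was lower, so this share restates the pattern and cannot decide on sequence. The endodermis cannot be told apart from background and handling, since J0571, which shares it with other tissue, shifted by 0.0276 for heat shock and 0.162 for ribosomal genes, against 2.35 and -0.879 in SCR. A heat or handling stress of the plants behind replicates 2 and 3 may be a candidate explanation, and it was not tested.

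Root hair genes were higher in WOL, though the label names the stele. More mature cells would lower Stage I genes and raise Stage III genes in WOL. The 3765 probe sets at least 2-fold higher in Stage I than in Stage III had a median change of 0.0429 (SD 0.275 between the WOL arrays), against 0.0939 for all probe sets. The 3729 higher in Stage III had a median of 0.468. Cell division genes, which more mature cells would lower, had a mean of 0.285 in WOL, against lines that include SCR (-0.72). These values point different ways, so maturity stays open. Root hair cells in the sample would raise genes by their level in Stage III, and across the 15 genes rho was 0.618 (one-sided permutation p = 0.00787, genes not being independent replicates), but an equal fold in all genes would give 0.457, and the difference of 0.161 is within its bootstrap SD of 0.264. More mature cells and root hair cells cannot be told apart from each other or from expression in the stele itself.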

How the results depend on the processing

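In this part, the tests with the spike-in class and with WOL and GL2 against each other only were chosen only after the result was seen.

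The counts of probe sets past the threshold stayed within 1.5 times their first value under all alternatives run, except the following. With calls of at least 2-fold, SCR had 2483 and Stage II against Stage I 2723, by construction. With the spike-in batch block SCR had 405 and J0571 against SCR 377, and with high spike-in arrays only 389 and 344, with fewer SCR arrays in use. Stage II against Stage I had 2797 with high and 2689 with low spike-in arrays only, and Stage III against Stage II 4532 with low spike-in arrays only, on fewer arrays. With WOL and GL2 against each other only, WOL had 2277, and the cause was not tested.

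Leaving out 1 array gave 1155 to 3057 for J3411, 1750 to 5095 for SCR, 738 to 2036 for WOL, 1605 to 3566 for GL2, 408 to 1382 for J0571, 475 to 3333 for J0571 against SCR and 403 to 2428 for GL2 against J3411. The stage counts stayed within 1.5 times. With an estimated correlation, the lists past the threshold numbered 2 of 9 for J3411, 0 of 12 for SCR, 0 of 10 for WOL, 3 of 10 for GL2, 2 of 9 for J0571, 0 of 6 for J0571 against SCR, 0 of 6 for GL2 against J3411, 0 of 5 for Stage II against Stage I, 0 of 16 for Stage III against Stage II and 0 of 15 for Stage III against Stage I. Most list calls therefore rest on the preset correlation.

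Both with the spike-in batch block and with high spike-in arrays only, 6 list means changed sign. Among the line arrays only SCR has low-class arrays, so both settings reduce SCR to its replicate 1. They are thus the same comparison for SCR and not separate checks. In SCR, root cap genes went from -1.65 to 0.02, heat shock went to -0.097, plastid-encoded genes to 0.81 and mitochondrion-encoded genes to 0.29. In J0571 against SCR, heat shock went to 0.12 and plastid-encoded genes to -0.92. These sign changes rest on SCR replicate 1, and why it differs from replicates 2 and 3 was not tested. No gene call examined changed sign. The genes examined were those named in the text, and among list members those whose call held under the alternatives were preferred. The gene counts that follow therefore favour stable genes and do not show how often calls hold in general. With high spike-in arrays only, 25 gene calls ended and 179 held, and over all arrays left out in turn 98 ended and 2274 held. Quantile normalization ended 7 list calls and added 1. The balance of higher and lower calls was close to even in several comparisons and turned under these settings. Quantile normalization turned it for J3411 (1232 higher and 1220 lower), J0571 (531 and 574), Stage II against Stage I (2243 and 2129) and Stage III against Stage II (3141 and 4282). For J3411 it also turned with 2-fold calls (927 and 899) and without WOL replicate 2 (1002 and 995). For J0571 it also turned among Columbia lines only (618 and 739), with the spike-in batch block (679 and 779), with high spike-in arrays only (621 and 740), and without SCR replicate 1 (688 and 694) or 3 (505 and 525). For Stage III against Stage II it also turned with the dim filter (2980 and 3646), no pseudocount (3414 and 3425), the replicate block (4155 and 4157) and the spike-in batch block (4104 and 4166). With high spike-in arrays only it turned for Stage II against Stage I (1489 and 1308) and Stage III against Stage I (4143 and 4086).

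The labels do not say that equal replicate numbers were handled together. With the replicate block, Stage II against Stage I had 5929 calls and SCR 3544, and residuals of equal replicate numbers correlated by 0.0981 to 0.292 between stages. Signals near the background of 14.78 limit the folds, and the lower bounds cannot rank genes that are near it.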

Other observations

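In this part, no tests were chosen after the result was seen, apart from values within the high spike-in class and the splits that part every pair of equal replicate numbers.

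The stem cell niche genes AGL42, a MADS-box gene, and BBM were the members of their list that were measured. AGL42 was higher in WOL, at 58.7 ± 7.64 (SD, n = 3) against 18.6 ± 20.4 (n = 12), adjusted p = 0.00327, and in SCR, at 49.7 ± 9.63 against 20.8 ± 24.1, adjusted p = 0.00569. It was lower in J3411, at 1.91 ± 1.27 against 32.8 ± 23.9, adjusted p = 0.000741, and in GL2, at 7.89 ± 8.00 against 31.3 ± 25.4, adjusted p = 0.0418. Within the high spike-in class the call in SCR ended (adjusted p = 0.301). The call in GL2 was fragile: it ended with no pseudocount (0.0908), after quantile normalization (0.117), within the high class (0.0837) and without any of 10 single arrays. These were J3411 replicate 2 (0.0623), SCR replicates 2 (0.0587) and 3 (0.0579), WOL replicates 1 (0.0595), 2 (0.0569) and 3 (0.0632), GL2 replicates 1 (0.119) and 3 (0.33), and J0571 replicates 1 (0.0567) and 2 (0.0557).

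BBM was lower in SCR, at 9.15 ± 7.12 (SD, n = 3) against 32.7 ± 19.6 (n = 12), adjusted p = 0.0281. That call ended without SCR replicate 2 (0.222) or 3 (0.107), with no pseudocount (0.0959) and within the high spike-in class (0.717). BBM was also lower in GL2, at 6.28 ± 4.78 against 33.5 ± 18.7, adjusted p = 0.00508, a call that ended without GL2 replicate 3 (0.0591). It was higher in J0571 than in SCR, at 50.9 ± 12.9 against 9.15 ± 7.12, adjusted p = 0.0138, a call that ended without SCR replicate 2 (0.0675), without J0571 replicate 1 (0.0763) and within the high class (0.309). It was lower in GL2 than in J3411, at 6.28 ± 4.78 against 32.4 ± 9.68, adjusted p = 0.025, a call that ended without J3411 replicate 1 (0.129) or 2 (0.0702) or GL2 replicate 3 (0.11).

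Along the root the genes moved apart. BBM fell from 52.2 ± 23.8 (SD, n = 4) in Stage I to 8.27 ± 5.52 (n = 4) in Stage III, adjusted p = 0.000331, or 0.0995 within the high spike-in class. AGL42 rose from 49.1 ± 7.52 to 105.6 ± 27.4, adjusted p = 0.000541.

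Chance was tested by regrouping the arrays. For the lines, 100 splits of the 15 arrays were compared, and each split regrouped all lines together. For each line, 1 split of 100, the real one, gave as many calls. Chance can therefore be excluded only for the grouping into lines as a whole. The splits cannot exclude it for any single line, since real differences of the other lines widen the spread within regrouped arrays and lower their counts. The highest other split gave 109 for J3411 (2341 in the real one), 1222 for SCR (3974), 614 for WOL (1514), 2009 for GL2 (2908) and 518 for J0571 (1066). For the stages, 1 of the 35 free splits, the real one, gave as many calls. Arrays with equal replicate numbers deviated together, so free splits are not a fair measure of chance. Only 8 of the 35 splits part every such pair, too few to exclude chance. The highest other of the 35 splits gave 2 for Stage II against Stage I (4564), 1 for Stage III against Stage II (7038) and 1 for Stage III against Stage I (9806). For J0571 against SCR (2036, highest other 14) and GL2 against J3411 (1222, highest other 42), 10 splits are too few.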
